A study of Homo sapiens with 70 samples.

How the data were processed

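Hep3B and Huh7 hepatocellular carcinoma cells were treated for 24 h with DMSO, 5 µM GW3965, 2 µM sorafenib or both, and 70 poly-A RNA-seq libraries were assigned to 8 groups from their labels. The submitters' processing notes name edgeR, with no version, and the builds hg19 and GRCh37. The aligner, the counting of reads, the normalization and the kind of edgeR test are not given in the sources used here. Per the file headers, the authors compared each drug group with the DMSO group of the same line and deposited, for each RefSeq transcript, a mean log2 CPM and a log2 fold change. The authors also deposited an unadjusted p-value and an FDR for each transcript, per the file headers. The authors marked 1 representative transcript for each gene symbol, and gave the number of libraries with a nonzero count, which ran from 1 to 70. Of the 32321 transcripts, 21317 had a nonzero count in every library. No values of single libraries were used, so depth per library, replicate spread and outlying libraries could not be examined, and the precision of a value is known only through the authors' p-value.

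The columns were checked before use. The linear values of the mean log2 CPM summed to between 1004860 and 1008670 over the transcripts of a table, and representative transcripts took 56.3% of this sum in the first Hep3B table. Benjamini-Hochberg adjustment of the p-values over all 32321 rows gave the deposited FDR in every row, to within 1e-09. The direction of the fold change was checked from the DMSO level that each pair of columns implies. With the fold read as drug over DMSO, that level differed between tables of a line with an SD of 0.00220 to 0.0136 (log2), and with the reverse reading 0.286 to 0.609. The SD leaves out a constant offset between tables. In the first reading the largest median difference was -0.080 in Hep3B, GW3965 against sorafenib, and 0.044 in Huh7, the table labelled GW3965 against both drugs. A p-value was listed as 0 for at most 14 rows of a table.

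Genes were counted as called at the authors' FDR under 0.05 on the representative transcript, and no test of the 6 drug against DMSO comparisons was added. The authors' edgeR tests were not rerun. Before the data were examined, the design, 22 gene lists and the rule for named genes were fixed, with a set of alternatives of which only the FDR threshold of 0.01 could be run on these tables. The other alternatives were chosen after the data had been seen. The rule took, per comparison, the 5 highest and the 5 lowest called log2 fold changes at a mean of at least 2 CPM, up to 4 members of each described list with the largest changes, and 15 genes named in every case. Some genes that the rule takes are not reported here. Older gene symbols were matched through a table of symbols that lacked some of them, so 5 list members that the authors' deposited tables hold under older names, SC5D, SLC51A, SLC51B, TIGAR and CXCL8, are missing from the counts and tests of their lists. Matching them through the synonyms of the RefSeq gene table was added after the data had been seen, as an alternative. The list of mitochondrial-encoded transcripts had 0 members in the tables. Lists were tested against the other expressed genes of a table with the rank test cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal score of the p-value, with a preset inter-gene correlation of 0.01, for lists with at least 5 expressed members, and with Benjamini-Hochberg adjustment over the lists of a comparison. A correlation could not be estimated without values of single libraries, so an assumed value of 0.05 was tried instead. The use of expressed genes as background was chosen after seeing the data.

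The design fixed beforehand planned count-based edgeR tests, and no test of its own where the tables hold only the authors' fold changes. Both drugs against each drug, the departure from additivity and the differences between the lines would then have had no test. An approximate test was added after the data had been seen. The standard error of a log2 fold change was taken as its size divided by the normal score of its p-value, was replaced by the median of its expression bin (20 bins) where the p-value exceeded 0.5, and was never taken below that median. Differences of fold changes were divided by the root of the summed squared errors, and 2-sided normal p-values were adjusted by the Benjamini-Hochberg method. The shared DMSO libraries make contrasts within a line share error that this sum counts more than once. The set of genes was chosen in steps, first all genes, then at least 2 CPM in each table, and last a mean of at least 2 CPM over the tables of the contrast, where the mean was taken over the log2 values. The last is reported because a minimum in each table removes genes that start low, and the others are given with the alternatives. Tested on simulated counts for the Hep3B departure from additivity over 11648 genes, the approximate test found 100.0% of genes departing by 2 (log2), 51.4% of those departing by 1 and 0% of those departing by 0.5. For Huh7, over 11491 genes, these shares were 91.7%, 38.6% and 0%, and 0 unchanged genes were called in either simulation. The simulated depth and dispersion were assumed, and the simulated p-values came from t-tests on log2 CPM and not from edgeR. These shares therefore describe the method on such p-values. They give neither its rate of false calls on the authors' edgeR p-values nor the power of the study. The list test, on simulated scores of 11000 genes, called 99.5% of shifted lists and 0.125% of unshifted ones. These scores were independent between genes, so the shares do not hold for lists whose members vary together. The reference annotation used here belongs to another genome build than the authors' and gave no coordinates. Transcript length and GC content came from its GENCODE transcripts, matched by RefSeq accession, with a value for 96.4% of the genes tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.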

Results

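Poly-A RNA was sequenced from Hep3B and Huh7, both established human hepatocellular carcinoma lines, after 24 h with vehicle (DMSO), 5 µM GW3965, 2 µM sorafenib or both drugs. GW3965 is a synthetic agonist of the liver X receptors (LXR), nuclear receptors that switch on genes of cholesterol efflux and fatty acid synthesis. Sorafenib is an inhibitor of RAF and of several receptor tyrosine kinases that is used against liver cancer. The 70 libraries comprised 9 in each of the 4 Hep3B groups, 8 each in the Huh7 groups labelled DMSO and GW3965, and 9 each in the Huh7 groups labelled sorafenib and combination. The values analysed here were the authors' 6 tables of edgeR comparisons, 1 for each drug arm of each line against the DMSO group of the same line. Each table gave a mean log2 CPM, a log2 fold change, a p-value and an FDR for 32321 transcripts of 20090 gene symbols, and every gene below stands for its representative transcript as the authors marked it. Values of single libraries were not analysed here, so the depth of each library is unknown and no spread between replicates could be computed. The labels do not say whether the libraries of a group came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical. A transcript counted as expressed at a mean of at least 2 CPM.

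The number of genes at the authors' FDR under 0.05 was higher with both drugs than with either drug alone in each line. In the authors' deposited table for Hep3B, GW3965 changed 1365 genes (906 higher and 459 lower). Sorafenib changed 6971 Hep3B genes in the authors' deposited table (3484 higher and 3487 lower), and both drugs together changed 9962 (5218 higher and 4744 lower). For Huh7, the authors' deposited table labelled GW3965 held 4099 calls (1835 higher and 2264 lower) and the one labelled sorafenib held 411 (251 higher and 160 lower). With both drugs, 8361 Huh7 genes were called in the authors' deposited table (4891 higher and 3470 lower). Changes of 2-fold or more, higher and lower, numbered 69 and 3 for Hep3B with GW3965, 856 and 357 with sorafenib, and 1601 and 1073 with both, in the authors' deposited tables. The median log2 fold change of all genes was 0.16 in the authors' deposited table for Huh7 with both drugs and lay within 0.1 of 0 in the other 5 tables. Over expressed genes that median was 0.07, and subtracting each table's expressed-gene median turned the direction of no named call.

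**Figure D1:**
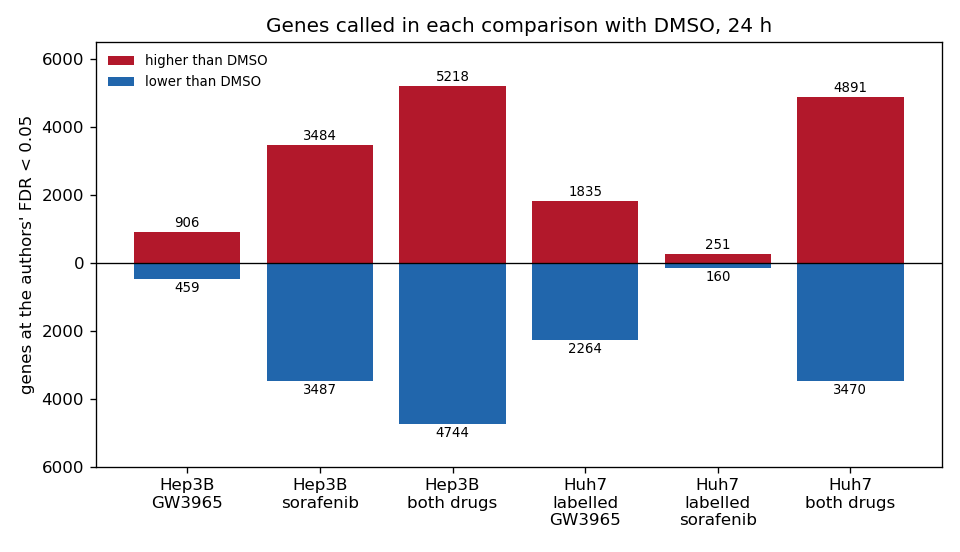
Number of genes higher (red, above 0) and lower (blue, below 0) than DMSO at the authors' FDR under 0.05, in each of the 6 comparisons. The comparison labelled sorafenib in Huh7 has 251 higher and 160 lower genes, against 3484 and 3487 for sorafenib in Hep3B.

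Which genes the LXR agonist alone changed in Hep3B was the first comparison. ABCG1 (NM_016818), a sterol efflux transporter and LXR target, had the highest fold change in the authors' deposited table, with a log2 fold change of 5.99 (edgeR FDR = 2.72e-255). Also among the 5 highest in the authors' deposited table were the lipogenic genes FASN (2.00), SCD (1.97) and SREBF1 (1.96). The 5 lowest were DBP (-1.25), RARB (-1.05), MMP11 (-0.99), ZNF467 (-0.98) and RFX6 (-0.93) in the same authors' deposited table. Of the LXR targets, 15 of 19 rose and 1 fell (16 and 1 adjusted over the list alone) in the authors' deposited table, and the list ranked above other expressed genes (limma cameraPR, adjusted p = 5.90e-08). ABCA1, which carries cholesterol to apolipoproteins, rose by 1.58 and MYLIP by 1.87 in the authors' deposited table.

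Lipid synthesis genes rose with GW3965 in Hep3B. Among genes of fatty acid synthesis and desaturation, 15 of 18 rose and 2 fell (15 and 2 adjusted over the list alone) in the authors' deposited table, with GPAM at 1.58 and ACACA at 1.24 (limma cameraPR adjusted p = 2.06e-06). That list shares lipogenic genes with the list of LXR targets. Of the genes of cholesterol synthesis and uptake, 23 of 24 rose and 0 fell (23 and 0 adjusted over the list alone) in the authors' deposited table, among them INSIG1 (1.29) (limma cameraPR adjusted p = 5.20e-11). Integrated stress response genes also ranked high (limma cameraPR adjusted p = 2.64e-07), and 16 of 22 rose and 0 fell (17 and 0 adjusted over the list alone) in the authors' deposited table. TRIB3, a pseudokinase induced by amino acid and ER stress, rose by 1.36 and the transcription factor ATF3 by 0.79, while DDIT3 stood at 0.07 in the authors' deposited table (edgeR FDR = 1). Transcriptional output of the ERK pathway rose in the authors' deposited table, where 10 of 15 rose and 0 fell (12 and 0 adjusted over the list alone), with EGR1 (1.16) and DUSP6 (0.33) as examples (limma cameraPR adjusted p = 2.97e-07). Genes of DNA replication and of mitosis shifted slightly down, with medians of -0.11 and -0.11 in the authors' deposited table (limma cameraPR adjusted p = 7.72e-06 and 5.90e-06). Of the replication genes 0 of 22 rose and 6 fell (0 and 12 adjusted over the list alone), and of the mitosis genes 0 of 20 rose and 5 fell (0 and 7 adjusted over the list alone), in the authors' deposited table. MKI67 stood at 0.09 and CCND1 at 0.18 there, neither past the threshold in the authors' deposited table. Log2 fold changes with GW3965 in Hep3B rose with transcript length, at a Spearman rho of 0.24 across 11044 genes, which are not independent replicates. Whether this trend contributes to the small list shifts was not tested.

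Sorafenib alone was compared with DMSO in Hep3B next. The highest changes in the authors' deposited table were KLHDC7B (5.23), PRPH (4.72), the netrin receptor UNC5B (4.21), LAMP3 (4.07) and FUT1 (3.95). The lowest in the authors' deposited table were CGA (-3.55), SLC6A14 (-3.42), CHODL (-3.24), the histidine-degrading enzyme gene HAL (-3.03) and the immediate early gene EGR1 (-2.86). ERK output genes fell together. In this list, 0 of 15 rose and 13 fell (0 and 13 adjusted over the list alone) in the authors' deposited table, with DUSP6 (NM_001946), the phosphatase that ERK signalling induces, at -2.40, ETV4 at -2.08 and SPRY4 at -1.99 (limma cameraPR adjusted p = 7.84e-06). CCND1, the gene of cyclin D1, fell by 0.91 on the log2 scale in the authors' deposited table. Of the integrated stress response genes, 22 of 22 rose and 0 fell (22 and 0 adjusted over the list alone) in the authors' deposited table (limma cameraPR adjusted p = 5.17e-12). The examples with the highest values were CHAC1 (3.56), STC2 (3.34) and TRIB3 (3.29), with ATF3 (NM_001040619) at 3.12 and DDIT3 at 2.48 in the authors' deposited table.

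Cell cycle and sterol genes moved the other way with sorafenib in Hep3B. Of the DNA replication genes, 0 of 22 rose and 21 fell (0 and 21 adjusted over the list alone) in the authors' deposited table, with RRM2 (-1.68), UHRF1 (-1.58) and CCNE1 (-1.51) (limma cameraPR adjusted p = 3.23e-11). Of the mitosis genes, 0 of 20 rose and 19 fell (0 and 19 adjusted over the list alone), and the proliferation marker MKI67 fell by 1.33 on the log2 scale, in the authors' deposited table (limma cameraPR adjusted p = 1.12e-07). In the list of cholesterol synthesis and uptake, 1 of 24 rose and 22 fell (1 and 23 adjusted over the list alone) in the authors' deposited table, including INSIG1 (-1.47) and HMGCS1 (-1.21) (limma cameraPR adjusted p = 4.31e-09). The lipogenic genes split, since FASN (-1.22), SCD (-1.16) and SREBF1 (-0.88) fell and DGAT2 (1.95) and ACACB (1.19) rose in the authors' deposited table. As a list, fatty acid synthesis did not pass the test (limma cameraPR adjusted p = 0.601), and neither did the LXR targets (limma cameraPR adjusted p = 0.601), of which 5 of 18 rose and 7 fell (5 and 7 adjusted over the list alone) in the authors' deposited table. The NF-kB and cytokine list did not pass (limma cameraPR adjusted p = 0.142), although the chemokine genes CCL20 and CXCL5 were called lower, at -2.55 and -2.33, in the authors' deposited table.

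With both drugs, Hep3B cells carried the LXR target rise and the stress response rise at once. The highest values in the authors' deposited table were KLHDC7B (6.70), ABCG1 (6.46), UNC5B (5.79), LAMP3 (5.55) and KRT17 (5.14). The lowest were CXCL1 (-4.54), the glucose transporter gene SLC2A2 (-4.48), CXCL10 (-4.47), DKK1 (-4.26) and CCL20 (-3.97) in the authors' deposited table. Of the LXR targets, 14 of 19 rose and 3 fell (14 and 3 adjusted over the list alone) in the authors' deposited table (limma cameraPR adjusted p = 0.00565). Of the integrated stress response genes, 23 of 23 rose and 0 fell (23 and 0 adjusted over the list alone) in the authors' deposited table, with ATF3 (4.54), ALDH1L2 (4.31) and TRIB3 (4.04) as examples (limma cameraPR adjusted p = 3.50e-12). ER chaperone and unfolded protein response genes ranked high (limma cameraPR adjusted p = 5.63e-04), and 13 of 19 rose and 1 fell (13 and 1 adjusted over the list alone) in the authors' deposited table, among them HERPUD1 (2.41), ERN1 (2.36) and DNAJB9 (1.96). DNA replication genes ranked low (limma cameraPR adjusted p = 1.33e-09), and 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone) in the authors' deposited table, with CCNE1 (-2.84) and UHRF1 (-2.81). For cholesterol synthesis and uptake, 7 of 24 rose and 10 fell (7 and 11 adjusted over the list alone) in the authors' deposited table, and the list did not pass (limma cameraPR adjusted p = 0.445). The lipogenic genes SCD and FASN rose by 1.00 and 0.39 in the authors' deposited table. The FASN call ended when the p-values were adjusted over representative transcripts alone. Of the 8 measured metallothionein genes, which encode metal-binding proteins, 7 rose in the authors' deposited table with no minimum on expression, with log2 fold changes of 4.06 for MT2A, 3.87 for MT1X, 3.58 for MT1E and 3.02 for MT1G. These genes are near-identical copies, and how reads were shared among them is not given in the sources used here, so the value of each is uncertain. Secreted hepatocyte products ranked low (limma cameraPR adjusted p = 0.0478, or 0.135 at an assumed inter-gene correlation of 0.05), with TTR (-1.89) and AFP (-1.79), and 3 of 20 rose and 13 fell (3 and 13 adjusted over the list alone) in the authors' deposited table.

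Huh7 gave a different picture under the same labels, and its single-drug groups are called by their labels here. In the authors' deposited table labelled GW3965, ABCG1 stood at 0.75, ABCA1 at 0.28, SREBF1 at -0.07 and FASN at 0.12, and of these only ABCG1 passed the threshold. In the authors' deposited table labelled sorafenib, the same genes rose, ABCG1 by 3.82, ABCA1 by 1.30, SREBF1 by 1.63 and FASN by 1.39. ERK output fell in the authors' deposited table labelled GW3965, where 0 of 15 rose and 9 fell (0 and 10 adjusted over the list alone), with DUSP6 (-1.70), EGR1 (-2.61) and SPRY4 (-1.67) (limma cameraPR adjusted p = 1.12e-04). In the authors' deposited table labelled sorafenib, 1 of 15 rose and 0 fell (2 and 1 adjusted over the list alone), and DUSP6 stood at -0.02 (limma cameraPR adjusted p = 0.756).

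The table labelled GW3965 in Huh7 had its highest values at HSD17B14 (2.56), INHBE (2.49), AMHR2 (2.41), CYP3A7 (2.22) and NPNT (2.16) in the authors' deposited table. Its lowest were LFNG (-3.21), MYH4 (-3.05), CGA (-3.03), EGR1 and CCR6 (-2.26) in the authors' deposited table. Of the stress response genes, 18 of 22 rose and 1 fell (19 and 1 adjusted over the list alone) in the authors' deposited table, with CHAC1 (2.07), DDIT3 (1.35) and ATF3 (1.20) (limma cameraPR adjusted p = 6.79e-08). Mitosis genes fell as a list, and 0 of 20 rose and 19 fell (0 and 20 adjusted over the list alone) in the authors' deposited table (limma cameraPR adjusted p = 6.79e-08). DNA replication genes did too, as 0 of 22 rose and 14 fell (0 and 20 adjusted over the list alone) in the authors' deposited table (limma cameraPR adjusted p = 6.47e-06). Of the ER chaperones, 1 of 19 rose and 10 fell (2 and 12 adjusted over the list alone) in the authors' deposited table, with SDF2L1 (-0.68) and HSPA5 (-0.48) (limma cameraPR adjusted p = 0.00841). The LXR targets still ranked above other genes (limma cameraPR adjusted p = 1.97e-04), as 8 of 21 rose and 0 fell (13 and 1 adjusted over the list alone) in the authors' deposited table, with MLXIPL (1.09) as an example.

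The sterol efflux transporter gene ABCG1 led the table labelled sorafenib in Huh7. ABCG1 was followed in the authors' deposited table by CHAC1 (2.15), SREBF1, the bile acid transporter gene OSTalpha (1.59) (now SLC51A) and FASN. The lowest were KLF9 (-1.60), MMP11 (-1.33), F13B (-1.32), TP53INP2 (-1.17) and SLC17A8 (-0.96) in the authors' deposited table. Of the LXR targets, 14 of 20 rose and 0 fell (14 and 0 adjusted over the list alone) in the authors' deposited table (limma cameraPR adjusted p = 1.25e-05). Of the fatty acid synthesis genes, 14 of 18 rose and 0 fell (16 and 0 adjusted over the list alone) in the authors' deposited table, with ACSS2 (1.27) and GPAM (1.07) (limma cameraPR adjusted p = 6.93e-08). Cholesterol genes ranked high as well (limma cameraPR adjusted p = 8.62e-09), as 12 of 24 rose and 0 fell (16 and 0 adjusted over the list alone) in the authors' deposited table, with MVD (1.04). Integrated stress response genes again ranked high (limma cameraPR adjusted p = 6.58e-09), and 16 of 22 rose and 0 fell (19 and 0 adjusted over the list alone) in the authors' deposited table. Log2 fold changes in this table rose with the GC content of the transcript, at a Spearman rho of 0.38 across 11044 genes, which are not independent replicates. The same rho was 0.17 in the Huh7 table labelled GW3965, and -0.04 for GW3965 and 0.01 for sorafenib in Hep3B.

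With both drugs, Huh7 cells showed the LXR target and stress response rises together, as Hep3B cells did. Among the 5 highest values in the authors' deposited table were HKDC1 (4.89), a hexokinase family member, LAMP3 (4.58), DNAH17 (4.47) and ABCG1 (4.37). The lowest were CCR6 (-4.25), ATP2B2 (-3.55), ARG1 (-3.38), DKK1 (-3.31) and CCL20 (-3.28) in the authors' deposited table. Of the LXR targets, 13 of 21 rose and 1 fell (13 and 2 adjusted over the list alone) in the authors' deposited table, with ABCA1 (1.91) and SREBF1 (0.81) (limma cameraPR adjusted p = 0.00324). Of the cholesterol genes, 16 of 24 rose and 0 fell (16 and 0 adjusted over the list alone) in the authors' deposited table, among them MVD (1.11) and INSIG1 (0.91) (limma cameraPR adjusted p = 0.00487). Stress response genes ranked high (limma cameraPR adjusted p = 2.81e-10), and 21 of 22 rose and 1 fell (21 and 1 adjusted over the list alone) in the authors' deposited table, with ATF3 (3.93), TRIB3 (3.54) and DDIT3 (2.88). ER chaperone genes went both ways, as 6 of 19 rose and 8 fell (6 and 8 adjusted over the list alone) in the authors' deposited table, and the list did not pass (limma cameraPR adjusted p = 0.205). By the approximate test of the difference between the lines, 18 of 19 were higher and 0 lower in Hep3B (limma cameraPR adjusted p = 3.28e-09). Of the DNA replication genes, 0 of 22 rose and 21 fell (0 and 22 adjusted over the list alone) in the authors' deposited table, with RRM2 (-2.48) and UHRF1 (-2.12) (limma cameraPR adjusted p = 8.91e-11). Hepatocyte products ranked low (limma cameraPR adjusted p = 1.81e-04), and 2 of 22 rose and 14 fell (2 and 14 adjusted over the list alone) in the authors' deposited table, with the acute-phase gene HP (-2.88) and TTR (-1.59). ALB, the albumin gene, stood at -0.15 in the authors' deposited table (edgeR FDR = 0.242). The ERK output list ranked low (limma cameraPR adjusted p = 0.0444), with DUSP6 (-1.68) and EGR1 (-2.78) lower and MYC (1.71) higher in the authors' deposited table. Its adjusted p was 0.102 at an assumed inter-gene correlation of 0.05.

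**Figure D2:**
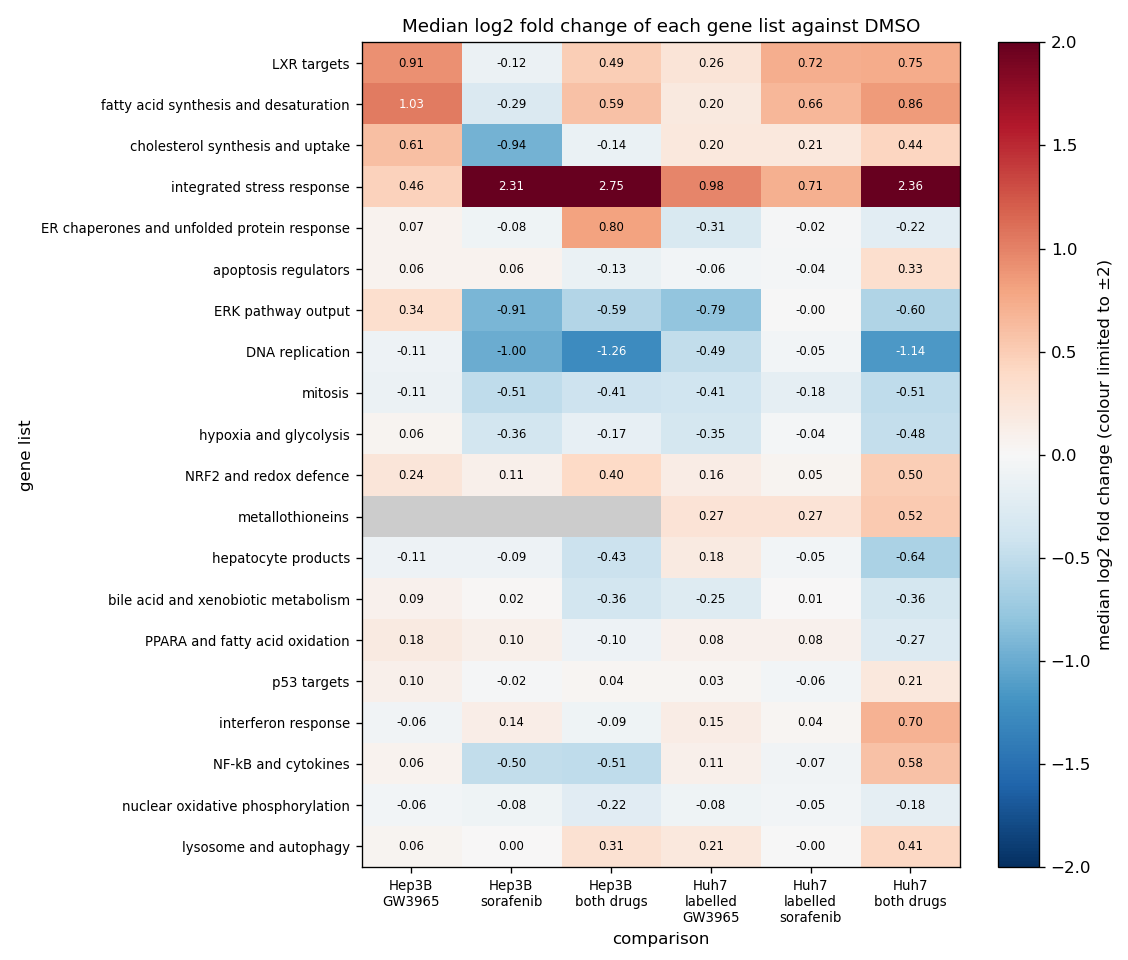
Median log2 fold change against DMSO of the expressed members of each gene list (rows) in the 6 comparisons (columns), with the value written in each cell. Cells with fewer than 5 expressed members are grey, and the stress response row reads 2.31 for sorafenib in Hep3B and 0.71 for the comparison labelled sorafenib in Huh7.

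How far the 2 lines shared each response was compared over 11444 genes with a mean of at least 2 CPM over the tables. Genes are not independent replicates, so the 9 correlations computed across genes, of which 5 are given, carry no p-value. The Hep3B changes with GW3965 had a Pearson r of 0.03 (Spearman rho 0.01) with the Huh7 table labelled GW3965 and 0.48 (rho 0.27) with the one labelled sorafenib. Those with sorafenib had an r of 0.23 (rho 0.17) with the Huh7 table labelled sorafenib and 0.59 (rho 0.55) with the one labelled GW3965. For both drugs the r was 0.67 (rho 0.63). Overlaps of calls in the authors' deposited tables were counted over the same genes, a set chosen after the data had been seen. Of the genes higher with GW3965 in Hep3B, 156 were also higher in the authors' deposited table labelled sorafenib for Huh7, against 15.8 for independent lists, and 188 in the one labelled GW3965, against 109. Of those higher with sorafenib in Hep3B, 898 were also higher in the authors' deposited table labelled GW3965 for Huh7, against 350, and 103 in the one labelled sorafenib, against 50.9. With both drugs, 2616 genes were higher in the authors' deposited tables of both lines, against 1431 for independent lists, and 2135 were lower in both, against 1063. Over all gene symbols of the authors' deposited tables, the set used first, the first of these overlaps was 160, against 11.3.

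**Figure D3:**
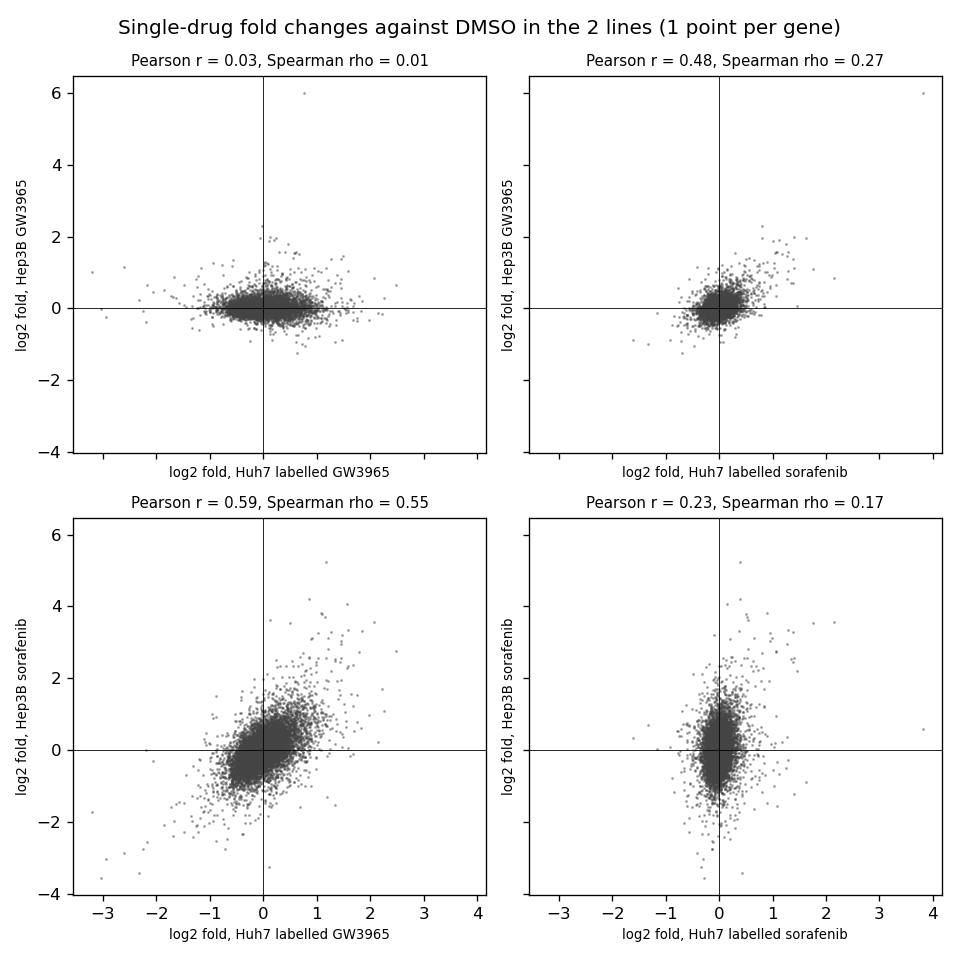
Log2 fold changes against DMSO in Hep3B (vertical axes) and in Huh7 (horizontal axes) for the single drugs, 1 point per gene. The Hep3B GW3965 changes have r = 0.48 with the Huh7 comparison labelled sorafenib and 0.03 with that labelled GW3965.

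The design also sets both drugs against each drug alone, for which no authors' table was used here. These differences of log2 fold changes were tested approximately, with standard errors implied by the authors' p-values, a test added after the data had been seen in place of no test. In Hep3B, adding GW3965 to sorafenib gave 3624 calls among 11635 genes, 1933 higher and 1691 lower. With the median difference subtracted the split turned to 1626 higher and 1932 lower. Without the minimum on expression it was 2056 higher and 3833 lower. ABCG1 was higher by 5.86 ± 0.26 (log2 difference ± implied SE), MT2A by 3.19 ± 0.53 and RBM24 by 3.31 ± 0.50. SREBF1 was higher by 2.18 ± 0.13 and SCD by 2.15 ± 0.17. The glucose transporter gene SLC2A2 differed by -3.50 ± 0.30 and the chemokine gene CXCL1 by -3.13 ± 0.26. Of the cholesterol genes, 18 of 24 were higher and 2 lower (limma cameraPR adjusted p = 5.16e-06), and of the ER chaperones 13 of 19 were higher and 0 lower (limma cameraPR adjusted p = 3.79e-06). Against GW3965 alone, both drugs gave 7364 calls in Hep3B, 3536 higher and 3828 lower. KLHDC7B was higher by 6.27 ± 0.44 and LAMP3 by 5.50 ± 0.26, while CCL20 differed by -4.63 ± 0.17 and EGR1 by -4.49 ± 0.22. Of the stress response genes, 22 of 22 were higher and 0 lower (limma cameraPR adjusted p = 1.86e-11). Cholesterol genes ranked low against GW3965 alone (limma cameraPR adjusted p = 1.21e-06). So did the LXR targets (limma cameraPR adjusted p = 0.0451, or 0.155 at an assumed inter-gene correlation of 0.05).

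In Huh7, both drugs against the group labelled sorafenib gave 5402 calls (3335 higher and 2067 lower), and against the group labelled GW3965 3445 (2340 and 1105). With the median difference subtracted, these splits became 2714 and 2672, and 1437 and 1663. Without the minimum on expression they were 5878 and 2759, and 5349 and 1258. Against the group labelled sorafenib, LAMP3 was higher by 4.43 ± 0.45 and HKDC1 by 4.39 ± 0.43, and DUSP6 differed by -1.66 ± 0.21 and CCR6 by -4.13 ± 0.27. Of the DNA replication genes, 0 of 22 were higher and 22 lower (limma cameraPR adjusted p = 3.67e-11). Against the group labelled GW3965, ABCG1 was higher by 3.62 ± 0.18 and ABCA1 by 1.63 ± 0.16, and HP differed by -3.07 ± 0.24. The difference of DUSP6 there was 0.02 ± 0.31 and did not pass the test.

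Departures from the sum of the single-drug log2 changes were tested in the same approximate way, and do not depend on which Huh7 single-drug group carries which label. In Hep3B 2565 of 11561 genes departed, 1249 above the sum and 1316 below it. MT2A lay above it by 2.87 ± 0.56, MT1E by 2.54 ± 0.58 and KRT17 by 2.01 ± 0.38. MT1E was under 2 CPM in the single-drug tables, at a mean log2 CPM of 0.06 for GW3965 and 0.51 for sorafenib, against 2.71 for both drugs. SLC2A2 departed by -3.03 ± 0.33, the neutrophil chemokine genes IL8 and CXCL1 by -2.86 ± 0.23 and -2.86 ± 0.27, and the kinase gene SGK1 by -2.48 ± 0.34. ER chaperone genes lay above the sum, as 11 of 19 were higher and 0 lower (limma cameraPR adjusted p = 1.68e-05). ABCG1 departed by -0.13 ± 0.32 and SCD by 0.18 ± 0.18, neither past the threshold. As lists, the LXR targets and the fatty acid synthesis genes ranked low, as 0 of 19 were higher and 7 lower and 0 of 18 were higher and 6 lower (limma cameraPR adjusted p = 0.0407 and 0.0206). At an assumed inter-gene correlation of 0.05 these adjusted p were 0.155 and 0.106. Of the stress response genes in Hep3B, 3 of 22 were higher and 9 lower, and that list did not pass (limma cameraPR adjusted p = 0.12). In Huh7 2426 genes departed, 1750 above and 676 below, and after subtracting the median departure of 0.14 the split was 844 and 1169. ATF3 lay above the sum by 2.06 ± 0.35 and DDIT3 by 1.23 ± 0.39, whereas HP departed by -2.48 ± 0.26 and SLC2A2 by -2.28 ± 0.30. DNA replication genes and hepatocyte products departed downwards, as 0 of 22 were higher and 14 lower and 0 of 21 were higher and 13 lower (limma cameraPR adjusted p = 5.83e-09 and 3.64e-08). Of the Huh7 stress response genes, 9 of 22 were higher and 1 lower, and the list did not pass (limma cameraPR adjusted p = 0.108, or 0.0235 when ranked by the log2 departure). SREBF1 departed by -0.75 ± 0.16, and the LXR targets and fatty acid synthesis genes ranked low, as 0 of 21 were higher and 7 lower and 1 of 18 were higher and 6 lower (limma cameraPR adjusted p = 0.00198 and 9.43e-04). Without the minimum on expression, 4711 Hep3B genes departed (1349 above and 3362 below) and 5344 Huh7 genes (3749 above and 1595 below).

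The same approximate test was applied to the difference between the lines under each label. For GW3965, 2817 genes differed, 1668 with a higher log2 fold change in Hep3B and 1149 with a lower one, and this split became 1229 and 1432 with the median difference subtracted. For sorafenib 4112 genes differed (2023 and 2089), and for both drugs 5060 (2038 and 3022, or 2441 and 2644 with the median difference subtracted). As Hep3B minus Huh7, ABCG1 differed by 5.24 ± 0.23 for GW3965 and FASN by 1.88 ± 0.17, and for sorafenib DUSP6 differed by -2.38 ± 0.14 and FASN by -2.62 ± 0.17.

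**Figure D4:**
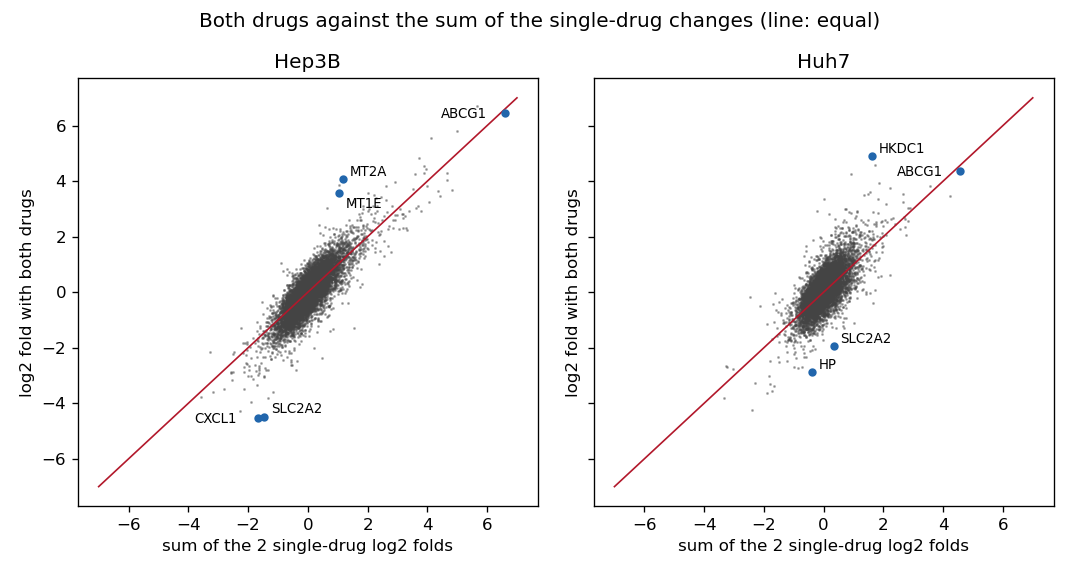
Log2 fold change with both drugs (vertical axis) against the sum of the single-drug log2 fold changes (horizontal axis) in each line, 1 point per gene, with the line of equality in red. In Hep3B, MT2A lies above the line by 2.87 and SLC2A2 departs by -3.03.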

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

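The tests of the line differences and of the labels, and that of a shift of the whole table, were chosen after the results were seen, and those of transcript length and GC content before. Differences between the lines under the same label, by the approximate test of the difference itself, are given first. If the Huh7 single-drug labels were exchanged, those for GW3965 and sorafenib would set different drugs against each other. Under the same label, 2817 genes differed between Hep3B and Huh7 for GW3965, 4112 for sorafenib and 5060 for both drugs. Among the genes named in every comparison whose changes were called in both lines with opposite signs, DUSP6 differed by 2.03 (Hep3B minus Huh7, log2) for GW3965. For sorafenib the differences were -2.50 for SREBF1, -1.57 for MYLIP, -1.96 for SCD, -2.62 for FASN and -1.30 for ACACA.

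The labels were kept as deposited, and each single-drug profile of Hep3B resembles the Huh7 profile labelled with the other drug. An exchange of these Huh7 labels, in the libraries or in the tables, is a candidate explanation; over 11121 genes outside every fixed list, the smaller of the gaps in Spearman rho, other drug's table minus same drug's, was 0.255. This restates the pattern on mostly the same genes, so an exchange and a biological difference between the lines, which was not tested as a cause, cannot be told apart by it. The LXR and ERK counts within Huh7 given next do not use Hep3B and lie the way an exchange would give. A response particular to Huh7 could give the same counts, so they do not decide. Both drugs being present in the wells labelled sorafenib, with sorafenib at the combination's dose, is argued against, since 0 of the 8 ERK output genes that fell with both drugs in Huh7 fell there, and 7 fell in the table labelled GW3965. This ERK count bears on sorafenib in those wells and does not argue against GW3965 in them. A lower dose of sorafenib in those wells was not tested. Both drugs at the combination's doses in the wells labelled GW3965 are argued against too, since by the approximate test 20 of 22 stress response genes were higher in the combination (limma cameraPR adjusted p = 8.57e-09). GW3965 with a lower dose of sorafenib in the wells labelled GW3965 is neither borne out nor excluded. Of the 13 LXR targets that rose with both drugs, 5 rose in that table, whereas 11 rose in the one labelled sorafenib.

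In Huh7, departures from the sum of the single-drug changes leaned upwards, with 72.1% of calls higher. Once the median departure was subtracted 41.9% of calls were higher, but subtracting a median pulls this share towards an even split by itself, so a shift of the whole table and a biological lean cannot be told apart. A trend with GC content may contribute, as the departure had a Spearman rho of -0.235 with GC content across genes, past the size of 0.2 set beforehand. The Huh7 single-drug changes, which the departure subtracts, had a rho of 0.384 (labelled sorafenib) and 0.170 (labelled GW3965). With both drugs the rho was 0.015. Whether this trend bears on the lists that departed downwards in Huh7 was not tested. Genes are not independent replicates, such a trend moves genes both ways, and the Hep3B departure had a rho of -0.176 with 48.7% of calls higher, so the trend does not by itself give a lean. For transcript length the rho was 0.144, between the bounds of 0.1 and 0.2 set beforehand, which leaves it open.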

How the results depend on the processing

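All settings here were added after the data had been seen, except the threshold of FDR under 0.01. At that threshold the calls fell to 857 for GW3965 in Hep3B, 2588 and 271 in the Huh7 tables labelled GW3965 and sorafenib, 2213 for both drugs against the group labelled GW3965 and 1298 for the departure from the sum in Huh7, 2281 for both drugs against sorafenib and 1379 for the departure in Hep3B, and 1772 for the line difference of GW3965. By construction, counting all transcript rows gave more, with 2405, 11946 and 16938 for GW3965, sorafenib and both in Hep3B, and 6956, 709 and 14304 for the same labels in Huh7. Without a minimum on expression the approximate tests called 8637 genes for both drugs against the group labelled sorafenib, 6607 against the group labelled GW3965 and 5344 for the departure in Huh7, with 5889 for both against sorafenib and 4711 for the departure in Hep3B. The Hep3B departure then split into 1349 higher and 3362 lower, against 1249 and 1316 in the main set, and both against sorafenib in Hep3B into 2056 and 3833, against 1933 and 1691. Line differences without the minimum numbered 5396 for GW3965 and 6811 for sorafenib, and for both drugs split into 2407 higher and 4907 lower in Hep3B. The cause was not tested for these.

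Counts of genes stayed within 1.5 times under adjustment over representative transcripts, with expressed genes only, with at least 2 CPM in each table, with centring and with no floor on the implied errors. Adjustment over representative transcripts ended the calls of FASN with both drugs and CYP1A1 with GW3965 in Hep3B. An inter-gene correlation of 0.05 ended 14 list calls of the 6 drug comparisons and started 0, and with both drugs in Hep3B 6 lists passed in place of 11, by construction of a wider test. Ranking by log2 fold change ended 1 list call and started 1, and all genes as background ended 1 and started 4, while the metallothioneins with both drugs in Hep3B, tested only with that background, passed as well (limma cameraPR adjusted p = 0.00336). Matching 5 more list members ended 0 list calls of the 6 drug comparisons and started 3, with 1 more, bile acid genes ranking low, for the departure in Huh7 (limma cameraPR adjusted p = 0.0183), and leaving out members shared with the stress response list changed 0. No paired analysis was possible because the tables hold no values of single libraries. For the same reason other normalizations, count filters and tools, another pseudocount, fits of the compared groups alone, leaving out replicates, an estimated correlation, combined libraries and other splits of the libraries were not run, so a chance division of libraries was not examined beyond the authors' p-values. Depth per library is unknown and the power of the approximate test on these data was not measured, so small departures are not excluded. The 0% found for simulated departures of 0.5 holds only for the assumed depth and dispersion and for p-values of t-tests.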

Other observations

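The test of paralogs in this part was chosen after the result was seen, as were the background, correlation, matching and shared-member settings of the list tests. Several gene groups not yet described passed the list test. With both drugs, NRF2 and redox defence genes ranked high in Hep3B and Huh7 (limma cameraPR adjusted p = 0.0208 and 0.0254), with SLC7A11 at 3.12 and 2.29 in the authors' deposited tables. Of this list 10 of 16 rose and 3 fell (10 and 4 adjusted over the list alone) in Hep3B, and 13 of 18 rose and 3 fell (13 and 3 adjusted over the list alone) in Huh7, in the authors' deposited tables. SLC7A11 is also a member of the stress response list, and with members of that list left out of the other lists these adjusted p were 0.0451 and 0.0498. At an assumed correlation of 0.05, with SLC7A11 kept, they were 0.08 and 0.083. Lysosome and autophagy genes ranked high in Huh7 with both drugs (limma cameraPR adjusted p = 0.00727), where 12 of 16 rose and 1 fell (12 and 2 adjusted over the list alone) in the authors' deposited table, with SQSTM1 (1.70) and NPC2 (1.38). In Hep3B with both drugs they went both ways, as 9 of 17 rose and 7 fell (9 and 8 adjusted over the list alone) in the authors' deposited table. Hypoxia and glycolysis genes ranked low in Huh7 with both drugs (limma cameraPR adjusted p = 0.00285), with LDHA (-1.47) and TPI1 (-1.01) lower and VEGFA (1.59) higher in the authors' deposited table. In Hep3B with both drugs 6 of 19 rose and 9 fell (6 and 9 adjusted over the list alone) in the authors' deposited table. Nuclear oxidative phosphorylation genes shifted down, at medians of -0.22 in Hep3B and -0.18 in Huh7 in the authors' deposited tables (limma cameraPR adjusted p = 0.0459 and 0.0152, or 0.125 and 0.0591 at a correlation of 0.05). In Huh7, 7 of 8 rose and 1 fell (7 and 1 adjusted over the list alone) among the metallothioneins with both drugs in the authors' deposited table (limma cameraPR adjusted p = 0.0254, or 0.0591 at a correlation of 0.05). PPARA and fatty acid oxidation genes ranked high with GW3965 in Hep3B (limma cameraPR adjusted p = 0.018, or 0.0636 at a correlation of 0.05 and 0.131 with all genes as background), with FABP1 (1.01) and PDK4 (0.85) in the authors' deposited table. With both drugs in Hep3B the NF-kB and cytokine list ranked low (limma cameraPR adjusted p = 0.049, or 0.125 at a correlation of 0.05). CXCL8 was not matched in that list, and with it the adjusted p was 0.0224. In Huh7 with both drugs 6 of 11 members of that list rose and 2 fell (6 and 2 adjusted over the list alone) in the authors' deposited table, and it did not pass (limma cameraPR adjusted p = 0.432).

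With both drugs 4 further lists did not pass at the main settings. The adjusted p of limma cameraPR in Hep3B and Huh7 was 0.665 and 0.0503 for apoptosis regulators, 0.843 and 0.211 for p53 targets, 0.945 and 0.211 for the interferon response, and 0.451 and 0.0523 for bile acid and xenobiotic metabolism. In Huh7 the apoptosis list, of which 11 of 18 rose and 1 fell (11 and 1 adjusted over the list alone) in the authors' deposited table, passed with all genes as background (limma cameraPR adjusted p = 0.00751), and the bile acid list passed when ranked by log2 fold change (limma cameraPR adjusted p = 0.0359). Once the list members left unmatched at first were added, the apoptosis and bile acid lists passed in Huh7 with both drugs (limma cameraPR adjusted p = 0.0497 for each), the former only through the adjustment over lists, and the bile acid list also ranked high in the table labelled sorafenib (limma cameraPR adjusted p = 0.0469, against 0.277 without them). The pro-apoptotic gene BBC3 rose by 1.28 in Hep3B and 2.20 in Huh7 with both drugs in the authors' deposited tables. In Hep3B, however, 4 of 17 apoptosis regulators rose and 7 fell (5 and 7 adjusted over the list alone) in the authors' deposited table. Markers of leukocytes, endothelium and stellate cells had 4 expressed members and were not tested, and with both drugs 0 of 4 rose and 2 fell (0 and 2 adjusted over the list alone) in Hep3B and 2 of 4 rose and 1 fell (2 and 1 adjusted over the list alone) in Huh7 in the authors' deposited tables. PDGFRB fell in both lines (-2.13 and -1.41), whereas COL1A1 and CD68 rose in Huh7 (0.99 and 0.80), in the authors' deposited tables.

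The metallothionein rise with both drugs in Hep3B led to a hypothesis, with its prediction written before the tested gene was looked at. Averaging log2 CPM over the tables left 2 metallothioneins at 2 CPM or more, MT1E and MT2A, and both were called above the sum of the single-drug changes. MT1E reached that minimum only through the table for both drugs, where it was high. MT1X was below that minimum and was not tested for a departure. If metal-responsive transcription were involved, the zinc exporter gene SLC30A1, which responds to the same transcription factor, should also lie above the sum. SLC30A1 departed by 0.94 (approximate 95% interval 0.514 to 1.37), at log2 fold changes of 0.14 with GW3965, 0.10 with sorafenib and 1.19 with both, which is consistent with that hypothesis, and other causes were not tested. Whether reads shared between these paralogs spread the rise of 1 gene over others cannot be told apart from separate rises, because the handling of such reads is not given in the sources used here.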
